A study of Caenorhabditis elegans with 3 samples.

How the data were processed

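Chromatin immunoprecipitation and sequencing of tagged NHR-25 was carried out by the authors in 3 biological replicates of L2 larvae of strain OP33, which form 1 group. The labels give a size range of 150 to 350 for replicates 1 and 2 and sonication for replicate 3. The aligner, the peak caller and their versions are not given in the sources used here. The authors mapped the data to ce11 and to ce10, per the labels, and a note deposited with the files states that regions were called for each replicate and for the 3 replicates pooled, against a control shared by all 3. That control was not analysed here. Each of these lists holds 30000 regions that mix peaks with background, as input for a reproducibility threshold (irreproducible discovery rate), and the optimal lists are the regions passing that threshold, per the same note.

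Each region carries a signal that the authors' peak caller gave it, whose scaling is not stated in the deposited files, and it was used to rank, filter and describe regions within a list. Each region also carries a −log10 q-value in the deposited lists, which is tied at its highest value for 3849 of the 4548 optimal regions, so ranks were taken from the signal. The summit is the position the authors deposited for each region as its offset from the start. Across the replicates' lists signals were compared by rank alone, and ratios of signals between lists were taken only in the closing section. Peak lists give no read counts, so the depth of each library is unknown and no error from depth could be attached to a signal.

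The ce11 lists were the main data, with gene models of Ensembl release 115 and the RefSeq sequence of the same assembly, while ce10 lists were used only where no annotation was needed and no coordinates were converted between builds. Coordinates are 1-based on ce11. Per replicate, the 4548 regions of highest signal were compared, as many as the optimal list holds. A region was supported by a replicate when it overlapped one of these by at least 1 bp, and chance was measured with 1000 circular shifts within chromosomes (200 for pairs of replicates). The promoter window ran from 1000 bp upstream to 200 bp downstream of any protein-coding transcript start. Shares of summits were tested with exact two-sided binomial tests against the share of the nuclear genome, with 95% Wilson intervals, and 200000 random positions gave the expected annotation classes. Motifs were searched on both strands within 50 bp of the summit and of the position 500 bp downstream, and were tested with exact McNemar tests, two-sided, with Benjamini-Hochberg adjustment over 8 motifs or over 2080 canonical 6-mers. Gene lists were tested with Fisher's exact test, two-sided, against the other protein-coding genes, with Benjamini-Hochberg adjustment over 18 lists at 0.05, and again against 10000 random lists matched on upstream intergenic distance. The motifs, gene lists, tests, main settings and most alternatives were fixed before the data were examined. Replicates come from separate biological replicates per the labels, and tests over sites or genes treat these as independent, which they are not.

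Ensembl gives the same name to several paralogous genes, so 495 genes were named by RefSeq instead, and each of 19971 genes in the background counted once. This was changed after the list results had been seen, and it ended the calls of the histone list and of the heat shock list; the names as Ensembl gives them were kept as an alternative. The genes ram-4 and lst-3 of the fixed lists were not matched by name. The genes named were nhr-25, those at the 20 strongest optimal sites that recurred in all 3 replicates and had a promoter window in reach, up to 4 bound members of highest signal for each list that passed and up to 2 for each that did not. Genes named for the half-site at their summit, further members of the heterochronic list and the Hox genes were chosen after their values were seen.

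Alternatives were the 2274 optimal regions of highest signal, ce10 lists, overlap of at least 50% of both regions, summits within 100 bp, 0.5 and 2 times as many regions per replicate, leaving out each replicate in turn, promoter windows of 500 and of 2000 bp, the nearest start, motif windows of 25 and 100 bp, an upstream flank and merging of overlapping regions, which left 4390. Leaving out a replicate meant keeping optimal regions supported by both others, since the optimal list itself could not be remade.

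The programs were tested on simulated data first. A site was planted in 15% of 4000 windows at random genome positions and was found in 14.8% of them afterwards. None of 2080 6-mers was called before planting, and 12 were called after it, among them the 4 inside the site. Random windows lack the GC difference between real summits and flanks, so this does not show how many 6-mers composition alone would call there. In 20 simulations over 19971 genes with 15% bound, a list raised to 40% was called 20 times, with 1 call of a list that shared no member with it. The raised list was the cuticle collagens, with 175 members, so power for shorter lists was not measured. Of 900 overlap searches, 0 differed from a search by brute force. Analyses were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.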

Results

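The binding of NHR-25 to the genome was profiled by chromatin immunoprecipitation and sequencing in whole Caenorhabditis elegans larvae of the L2 stage, of mixed sex. NHR-25 is the worm member of the FTZ-F1/SF-1 family of nuclear hormone receptors and is known for roles in the epidermis, in molting and in vulval development. The worms carried an integrated transgene that encodes NHR-25 with a GFP-FLAG tag at its C-terminus, together with the unc-119 mutation that such strains are built on. All 3 samples formed a single group of biological replicates, numbered 1 to 3 in the labels. The comparisons were therefore between replicates, between bound sites and the rest of the genome, and between the genes near bound sites and other genes. For each replicate the deposited list held 30000 regions, which mix peaks with background, and a thresholded list of reproducible regions (the optimal list) held 4548 regions on the ce11 build. Peak lists give no read counts, so the sequencing depth of each library is unknown here, and intervals given for shares of sites cover counting error only.

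The first question was which sites recurred in each replicate. The strongest nuclear site of the optimal list lay upstream of rpl-3, a gene for a protein of the large ribosomal subunit (chromosome III, 3867342 to 3867784), and it was found among the strongest 4548 regions of all 3 replicates, as were the sites of cdc-48.1, which encodes a p97-type AAA ATPase, and of puf-9, a Pumilio-family gene of the heterochronic pathway. Of the 4548 optimal regions, 2501 (54.99%) overlapped one of the strongest 4548 regions in each of the 3 replicates. A further 1212 (26.6%) did so in exactly 2 replicates, 734 (16.1%) in 1 and 101 (2.22%) in 0. Each replicate's strongest regions covered 78.1% ± 1.86 of the optimal regions (SD, n = 3). Of 5 equal parts of the list ordered by signal, the highest had 97.1% of its regions in all 3 replicates and the lowest 6.38%. Such a fall is built into the measure, which takes a fixed number of regions of highest signal per replicate. Of the optimal regions, 98.5 to 99.4% overlapped at least 1 of the 30000 regions of a given replicate, background regions included. In 1000 circular shifts of the replicates' regions within chromosomes, a mean of 0.331 and at most 9 regions were supported by all 3, a one-sided permutation p of 0.000999, the smallest these shifts can give. The optimal list was itself thresholded on the reproducibility of these replicates, so overlap above chance was built in and the shifts only give the level of chance. The share was 90.7% among the 2274 optimal regions of highest signal and 33.0% when overlap had to reach 50% of both regions. It was 31.5% when the strongest 2274 regions per replicate were compared and 82.5% with 2 times as many as the 4548.

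**Figure D1:**
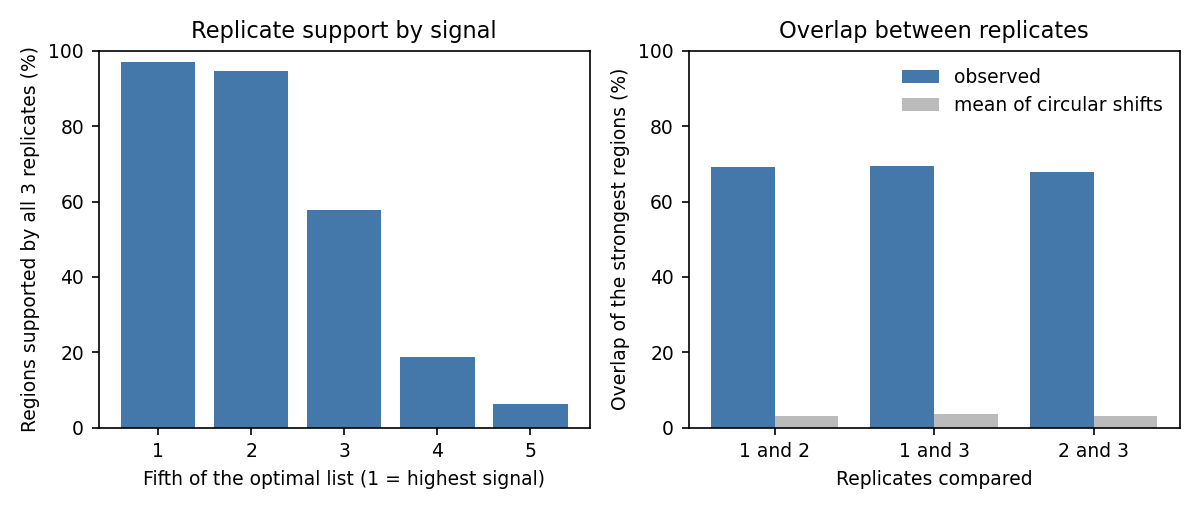
The left panel plots the percent of optimal regions supported by all 3 replicates (y axis) for each of 5 equal parts of the list by signal (x axis), from 97.1% in the highest part to 6.38% in the lowest. The right panel plots, for each pair of replicates, the percent of the strongest 4548 regions of one that overlapped those of the other (blue bars, 67.9 to 69.5%) beside the mean over circular shifts (grey bars, 3.22 to 3.72%).

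Replicate 3 carried other labels than replicates 1 and 2 for the source of the worms and for the fragmentation of the chromatin. Replicates 1 and 2 shared 69.3% of their strongest regions, replicates 1 and 3 shared 69.5% and replicates 2 and 3 shared 67.9% (mean 68.9% ± 0.853, SD over 3 pairs). Across optimal regions, the rank correlation of the replicates' signals was 0.678, 0.682 and 0.662 for the same pairs, with a mean of 0.674 ± 0.0103, mitochondrial regions included. These correlations are across regions, which are not independent replicates, and 1 pair against 2 allows no test of the difference in labels.

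The next comparison was between the places where the summits of the bound sites lay and the genome as a whole. Most summits stood close to the starts of protein-coding genes. Of 4524 nuclear summits, 2353 (52.01%, 95% Wilson interval 50.6 to 53.5%) lay in a promoter window, from 1000 bp upstream to 200 bp downstream of an annotated transcript start, and these windows made up 26.2% of the nuclear genome. The excess was 1.98-fold (exact binomial p = 4.776e-296), and the strongest regions of the replicates gave 50.5% ± 0.568 (SD, n = 3). Coding exons outside these windows held 1.59% of the summits against 18.8% of random positions, introns 16.9% against 26.9% and intergenic sequence 27.7% against 25.1%. The median distance from a summit to the nearest start was 714 bp, against 1299 bp for random positions, and 72.7% of the summits were upstream of that start. A remainder of 24.1% of the summits lay over 2000 bp from any protein-coding start. Neighbouring sites are not independent, and transcript starts in this organism are often sites of trans-splicing or lie within operons, so annotated starts need not be where transcription begins.

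The X chromosome, which carries nhr-25 itself, held 895 of the nuclear summits. This was 19.8% (18.6 to 20.97%), against 17.7% of the nuclear sequence, an excess of 1.12-fold (exact binomial p = 0.000247). The replicates gave 20.2% ± 0.370 (SD, n = 3). Chromosome III had 54.7 optimal regions per megabase, X 50.5 and I 49.2, while V had 35.4.

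**Figure D2:**
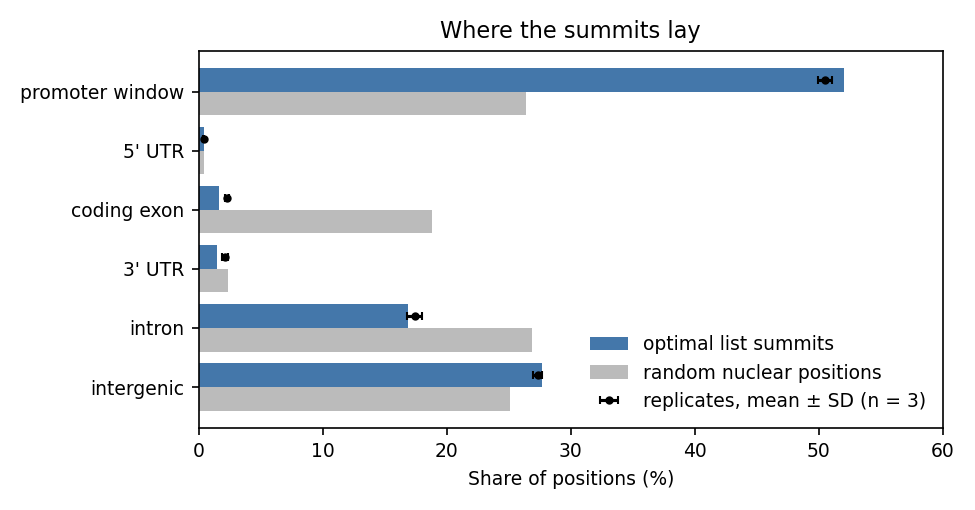
Bars give the percent (x axis) of optimal list summits (blue) and of random nuclear positions (grey) in each annotation class (y axis), and black points give the mean over the 3 replicates' strongest regions with the SD as error bars. Promoter windows held 52.01% of the summits against 26.4% of random positions, and coding exons 1.59% against 18.8%.

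At the nhr-25 gene (X, 13008493 to 13013964, plus strand), 15 optimal summits fell in the surrounding 40000 bp, where random nuclear windows of that size held 1.83 on average and 99.9% of 10000 held fewer. The strongest regions of replicates 1, 2 and 3 placed 14, 15 and 16 summits in the same window. The highest of these sites (X, 13008900 to 13009380, inside the gene) had a signal of 1135, rank 53 in the optimal list (32 among nuclear sites), and was supported by all 3 replicates, while sites at 13008048 to 13008736 and 13009628 to 13010091 had signals of 684 and 918. The unc-119 gene, whose wild-type copy is the usual marker of strains built this way, had 5 optimal summits in its own 40000 bp on chromosome III, more than in 89.2% of random windows. All 5 lay inside the gene. Those ranked 125, 143, 248 and 294 in the optimal list had signals of 827, 777, 608 and 567 and were supported by all 3 replicates. The other, at rank 2098 with a signal of 194, was supported by 2. Counted over all 30000 regions of replicates 1, 2 and 3, the window of nhr-25 held 26, 28 and 28 summits and that of unc-119 held 10, 12 and 15, where random windows held 12.1 to 12.2 on average. For nhr-25, 93.1 to 96.6% of random windows held fewer, and for unc-119 41.8 to 63.6%. Because the strain carries a transgene made from nhr-25, extra copies of this sequence can raise its coverage, and counts at both loci are described without a test.

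**Figure D3:**
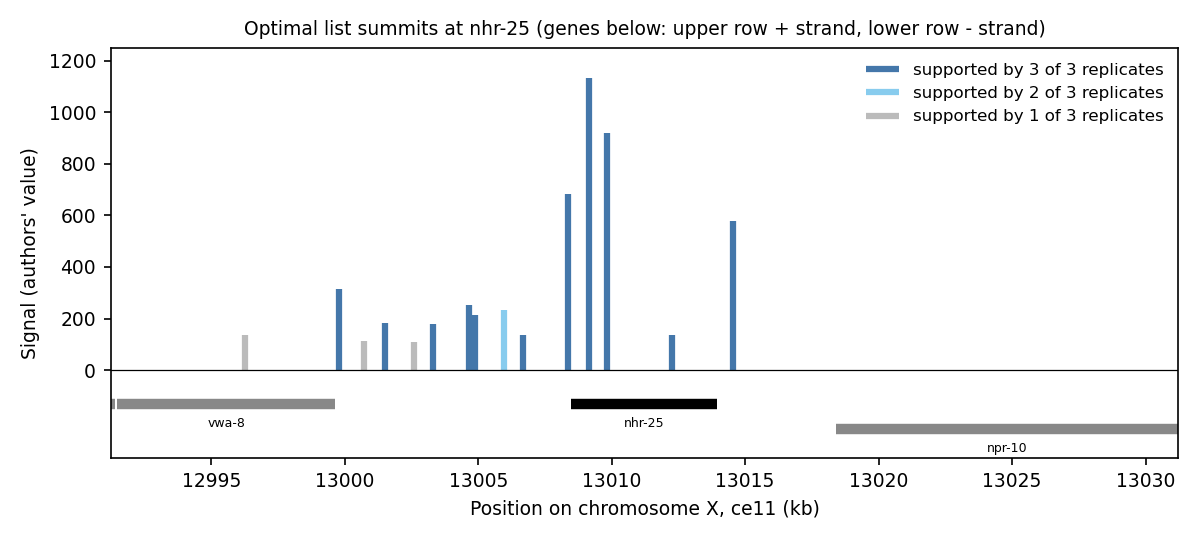
Vertical lines mark the 15 optimal summits by position on chromosome X (x axis, kb, ce11) and by the authors' signal (y axis), coloured by how many of the 3 replicates supported each, with gene models drawn below the axis. The 3 highest lines, at signals of 1135, 918 and 684, stand within nhr-25 or just upstream of its start.

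Sequence at the summits was then compared with sequence 500 bp downstream of the same summits, to ask whether the site known for FTZ-F1 family receptors was present. The extended half-site YCAAGGYCR lay within 50 bp of 64 summits (1.41%, 1.11 to 1.80%) and of 14 flanking positions (0.309%), a 4.57-fold excess (exact McNemar test, adjusted p = 1.373e-08 over 8 motifs). The replicates' strongest regions held it at 1.25% ± 0.178 of summits (SD, n = 3). Genes with the half-site at the summit of a promoter site included nlp-24, a neuropeptide-like protein gene (TCAAGGTCA, V, 11615839 to 11616529), gpd-2, which encodes glyceraldehyde-3-phosphate dehydrogenase (TCAAGGTCA, X, 3115062 to 3115378), and elt-3, an epidermal GATA factor gene (TCAAGGTCA, X, 13939385 to 13939774). These genes were chosen after their values were seen. The site at elt-3 had a signal of 127 and was found in 1 replicate's strongest regions, while those at nlp-24 and gpd-2, with signals of 484 and 265, were found in all 3. Of 5 equal parts of the summits by signal, from highest to lowest, the shares with the half-site were 0.994, 1.77, 1.22, 1.77 and 1.33%, with overlapping intervals. Among 100 column permutations of the consensus the median share of summits was 0.332% and the highest 3.25%, with 1 permutation at or above the consensus itself.

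The other 7 motifs were also more frequent at summits than beside them. Not all are independent: AGGTCA and the RORE-type site overlap in sequence, and both occur in TCAAGGTCA, a form of the extended half-site. The GAGA repeat was present at 24.6% of summits against 5.90% of flanks (exact McNemar test as for the others, adjusted p = 4.510e-137) and the E-box CACGTG at 5.88% against 1.83% (9.516e-24). The short nuclear receptor half-site AGGTCA stood at 6.56% against 2.92% (3.078e-16), and the RORE-type site known for NHR-23 at 5.73% against 2.74% (1.919e-12). The Grainyhead site AACCGGTT was found at 1.08% against 0.177% (3.622e-08) and the GATA site at 24.3% against 20.2% (3.680e-06). The PRDM site of BLMP-1 type was found at 4.80% against 3.74% (0.0142). By the same exact test this call, though not the direction, was lost in the 2274 regions of highest signal (4.49% against 3.69%, adjusted p = 0.195), without replicate 2 (4.69% against 3.90%, adjusted p = 0.151) and within 25 bp of the summit (2.08% against 1.64%, adjusted p = 0.142). Of all 2080 canonical 6-mers, 686 were more frequent at summits and 527 less frequent at an adjusted p under 0.05. Among those more frequent at summits, the lowest p-values belonged to GAGAGA, AGAGAG, AGAGAC and GACGCA, the last at 11.9% of summits against 1.92% of flanks, and among those less frequent AAAATT, at 19.8% against 42.5%, had the lowest. Summit windows were richer in GC (42.2%) than flanks (35.7%) and the nuclear genome (35.4%). Composition alone therefore favours 6-mers of high GC content. Motif tests used the same flanks without matching on GC. Composition may therefore also add to the excess of GC-rich motifs, the extended half-site included. At summits, 1 of 100 column permutations of that half-site, which keep its composition, reached its share. The permutations were compared at summits alone, so they do not test whether composition produced the excess over flanks.

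**Figure D4:**
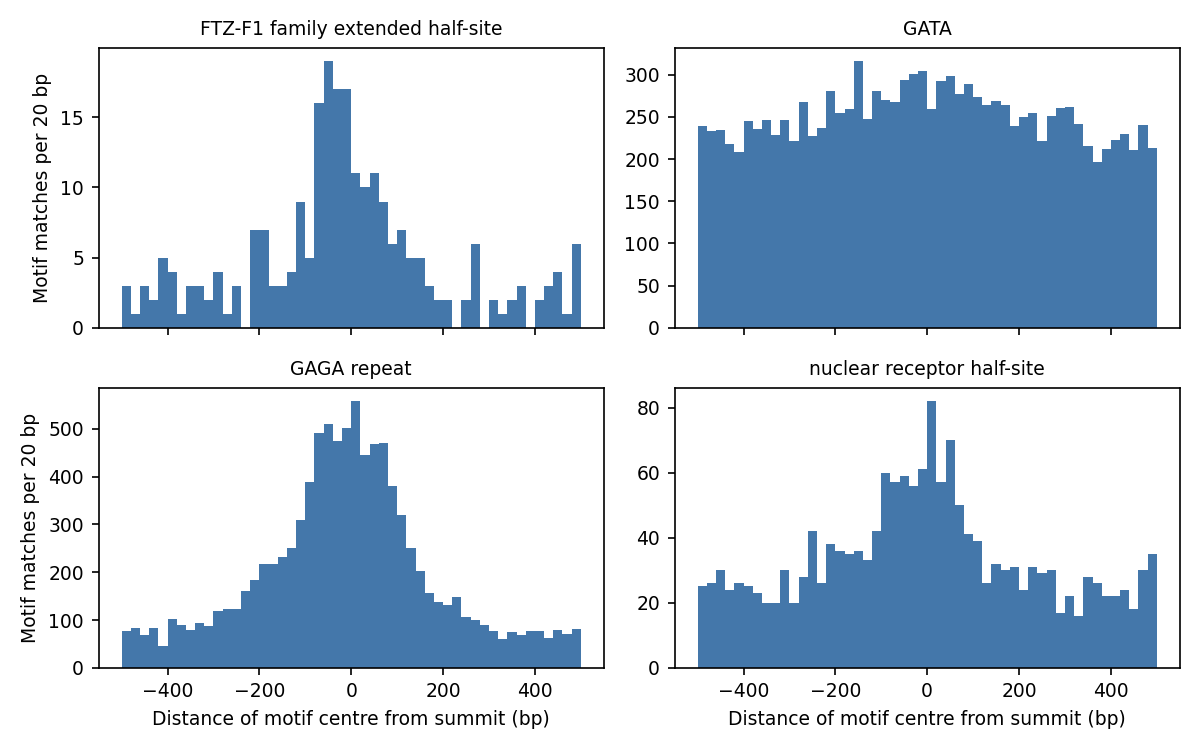
Bars count motif matches in 20 bp bins (y axis, a separate scale in each panel) by distance of the motif centre from the summit (x axis, bp) over 4524 nuclear optimal summits. The FTZ-F1 family half-site, the GAGA repeat and the nuclear receptor half-site rise towards the summit, while the GATA site is spread across the 1000 bp shown, as its shares of 24.3% at summits and 20.2% at flanks reflect.

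The sites of highest signal included many at ribosomal protein genes. Among the 20 strongest nuclear sites that recurred in all 3 replicates and had a protein-coding start in reach, with signals from 2859 down to 1233, those of the genes rpl-3 (2859), rpl-20 (2271, IV, 4749844 to 4750268), rpl-35 (2188, III, 7854488 to 7854918), rpl-15 (1851, IV, 654747 to 655119), rps-19 (1417), rps-1 (1306), rpl-12 (1286) and rps-12 (1233) belonged to the cytosolic ribosome. Others stood at iff-2 (1647), which encodes the translation factor eIF5A, at drr-2 (1452), an eIF4H-type gene, at larp-1 (1263), a La-related RNA-binding protein gene, at sec-61.G (1293), a subunit of the protein translocation channel, and at cox-5A (1247), a subunit of cytochrome c oxidase. The site of cdc-48.1 (2642) was at II, 10563395 to 10563763. The shared site of nhl-2 and tag-340 (1568) lay by a gene, nhl-2, whose product acts with microRNA complexes, and that of puf-9 (1244) was at X, 5840934 to 5841482. The genes hsr-9, ifet-1, lin-54, set-16, ska-3, wip-1, Y17G9B.5, K11H12.8, F54C9.14 and F32D8.13 had a start in the window of 1 of these shared sites, and the remaining sites were at tasp-1 with K01G5.10 (2194), nspc-17 (1363), H41C03.3 (1301) and the histone gene his-37 (1271). At shared sites, Y17G9B.5, hsr-9, ska-3, wip-1 and tag-340 had starts nearer the summit than rpl-20, rps-19, rps-12, larp-1 and nhl-2, respectively. At the others, rpl-15, rps-1, rpl-12, iff-2, drr-2 and sec-61.G had the nearer start. These 20 sites reach down to rank 27 among nuclear sites, since stronger sites without such a start or without support in all 3 replicates were passed over. None of the 20 sites had the extended half-site within 50 bp of its summit, which is the likeliest count for 20 sites at the share of 1.41% over all nuclear summits.

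The last comparison asked which groups of genes had bound promoters. In all, 2678 of 19971 protein-coding genes (13.4%) had an optimal summit in a promoter window, with nhr-25 and unc-119 set aside. A gene counted as bound through any of its annotated starts, and the tests were not corrected for the number of starts per gene. Cytosolic ribosomal protein genes were bound in 65 of 81 cases (80.2%, odds ratio 26.9, Fisher's exact test, adjusted p = 6.404e-41 over 18 lists). Heterochronic genes, which time larval cell fates, were bound in 8 of 14 (57.1%, odds ratio 8.63, Fisher's exact test, adjusted p = 0.00131): puf-9 and kin-20, a casein kinase gene, had sites with signals of 1244 and 992, lin-66 one of 424 and lin-14, a regulator of early larval fates, one of 343, while alg-1, lin-28, lin-42 and lin-46 were the other 4. Both lists passed without each replicate in turn. The size of the ribosomal excess depended on how sites were given to genes. With each summit given to its nearest start, its odds ratio was 5.56 (Fisher's exact test, adjusted p = 4.771e-12). That of heterochronic genes was 13.45 under the same rule. The microRNA genes lin-4, let-7, mir-48, mir-84 and mir-241 had no optimal summit in their windows and were outside the test.

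Wnt pathway and Hox genes were bound in 10 of 32 (31.3%, odds ratio 2.94, Fisher's exact test, adjusted p = 0.0432). The Dishevelled genes mig-5 (II, 8185024 to 8185379) and dsh-2 had sites with signals of 1104 and 397, lit-1, a Nemo-like kinase gene, one of 335 and apr-1, the APC homologue, one of 240. The Hox genes among them, lin-39, mab-5 and ceh-13, had sites ranked 3358, 4143 and 3821 in the optimal list, of which that of lin-39 was found in 2 replicates' strongest regions and those of mab-5 and ceh-13 in 1. This call was lost when sites had to recur in both other replicates, with an adjusted p of 0.186 without replicate 1, 0.438 without replicate 2 and 0.264 without replicate 3. It was also lost in the 2274 regions of highest signal (0.275) and with a window of 500 bp upstream (0.139).

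The remaining 15 lists did not pass the test in promoter windows. Cuticle collagens, products of the epidermis, had 28 of 175 members bound (Fisher's exact test as for each list, adjusted p = 0.437), with sites of signal 420 at col-38 and 317 at col-117. Molting genes had 8 of 30 (0.133), among them dab-1 (236), an endocytic adaptor gene, and nhr-23 (200), a nuclear receptor gene needed for molting. Epidermal and seam cell transcription factors had 6 of 18 (0.115), with elt-1 at 380, a GATA factor gene of epidermal fate, and myrf-2 at 311. Nuclear hormone receptors had 48 of 273 (0.133), with nhr-105 at 631 and nhr-35 at 412, and fatty acid and lipid metabolism had 8 of 31 (0.133), with fasn-1, the fatty acid synthase gene, at 291 and nhr-49 at 245. Apical matrix and cuticlin genes had 4 of 45 (0.657), with lpr-3 at 141 and noah-1 at 126. Hedgehog-related and Patched-related genes had 11 of 88 (1), with grl-21 at 297 and grl-4 at 243, and the EGF, Ras and Notch list had 3 of 21 (0.890), with sem-5 at 174 and lst-2 at 160. Heat shock and chaperone genes had 6 of 19 (0.119), with hsp-90 at 1057 and hsp-60 at 1006. This list passed the exact test in the 2274 regions of highest signal (adjusted p = 0.0167) and without replicates 1, 2 and 3 (0.0309, 0.0377 and 0.0388). Histone genes, which are near-identical copies that share reads, had 14 of 72 (0.275), with his-37 at 1271 and his-67 at 1066.

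The lists of markers of tissues other than the epidermis did not pass the test in either direction. Body wall muscle markers had 3 of 23 (Fisher's exact test as above, adjusted p = 1), with unc-112 at 266 and unc-60 at 142, and germline markers had 3 of 31 (0.890), with pie-1 at 442 and cgh-1 at 311. Neuron markers had 1 of 25 (0.362), snb-1 at 314, a synaptobrevin gene. Pharynx markers had 1 of 29 (0.275), peb-1 at 137, which carried the half-site CCAAGGTCA at its summit, and intestine markers had 0 of 19 (0.196). When each summit was given to its nearest start at any distance, 10 lists passed in place of 3, adding cuticle collagens, molting genes, Hedgehog-related and Patched-related genes, epidermal transcription factors, the EGF, Ras and Notch list, nuclear hormone receptors and lipid metabolism. Genes with long upstream regions can gather more summits under that rule: against random lists matched for upstream distance, 7 lists passed, without molting, Hedgehog-related and EGF, Ras and Notch genes. These lists still had 1.95, 1.49 and 1.96 times as many bound genes, respectively, as the matched lists had on average. Their lost calls therefore do not show that upstream length produced the excess.

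**Figure D5:**
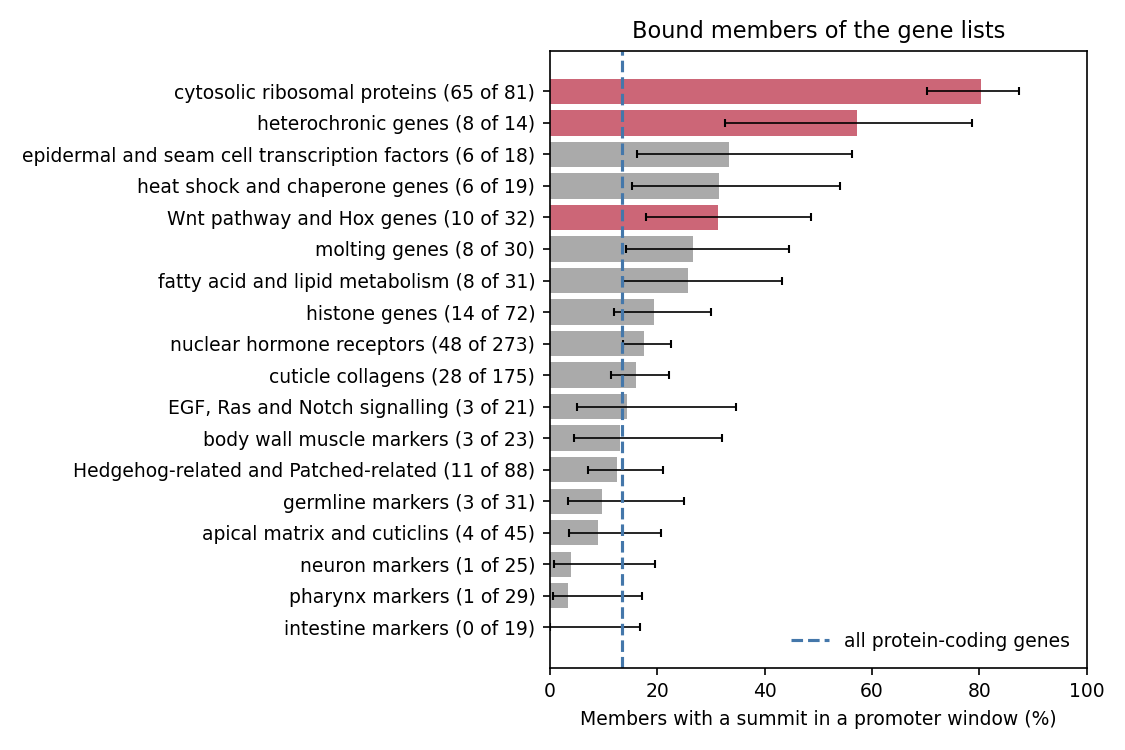
Bars give the percent of each list's members with an optimal summit in a promoter window (x axis), with 95% Wilson intervals as error bars and the members counted beside each name (y axis), and the dashed line marks the 13.4% of all protein-coding genes. Red bars are the 3 lists that passed the test, at 80.2, 57.1 and 31.3%, and grey bars are those that did not.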

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

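Of the tests weighed here, those of an exact half-site copy in mitochondrial DNA, of reads missing from replicate 2, of reads entered 2 times, of further libraries and of the half-site as the setter of signal were chosen after the results they measure had been seen, and the others were written down first. With 1 group in the design, no biological explanation that contrasts groups was tested.

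Mitochondrial DNA, which the comparisons of location, motifs and genes above leave out, was examined because regions appeared there in excess of its length: 24 optimal regions, where 0.626 would be there by length, and 28 regions in replicate 1 and 22 in replicate 3, where 4.13 would be. They included 15 of the 20 highest signals in the optimal list. An exact copy of the extended half-site was found 0 times in the mitochondrial genome, which argues against binding at such a copy, while Fisher's exact test of the half-site at mitochondrial against nuclear summits (p = 1) had too few summits to decide. Optimal regions covered 58.7% of the mitochondrial genome, as the abundance of this DNA in whole larvae may produce. Replicate 2 listed no mitochondrial region (exact Poisson p = 0.0161 against its length), and whether such reads were left out there before peaks were called or were scarcer in that library cannot be told apart without the reads.

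A second group of regions lies outside the optimal list although strong in every replicate: 117 of the strongest regions of replicate 1, 113 of replicate 2 and 113 of replicate 3 overlapped strong regions of both other replicates without overlapping an optimal region.

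Signals in the ce11 optimal list were a median of 2.02 times those of the pooled list at the same summits (quartiles 2.00 to 2.06), whereas the ce10 optimal list was the strongest 3347 regions of its pooled list with the same values. A change of unit alone is argued against by the coordinates, since 39.6% of ce11 optimal regions had those of a pooled region. For the addition of other libraries, the spread of the ratio between its quartiles was 1.03-fold, where adding 1 replicate to another gave 1.24 to 1.33. Those values come from single replicates, whereas the lists compared come from pooled ones, whose signals may vary less. The spread therefore cannot exclude added libraries. The ratio stayed between 1.9 and 2.1 in each of 5 equal parts of the list by signal, with 2.05 the farthest from 2. That band was set after the ratio had been seen, so it describes the ratio and is no test of its cause. A candidate explanation is that the same reads entered 2 times when this list was made. Results were therefore also computed from as many ce11 pooled regions as the ce10 list holds.

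Many of the strongest sites lay at ribosomal protein promoters. There, 0 of 65 bound genes had the extended half-site within 50 bp of the summit. This argues against binding at an exact copy within that distance at these genes. Set against 0.956% of other bound genes (Fisher's exact p = 1), the copies were too few to tell the groups apart. Whether the half-site raises the signal was not decided either, with median signals of 174 with it and 182 without (one-sided permutation p = 0.694, 95% bootstrap interval of the ratio 0.833 to 1.19). Summits at ribosomal protein genes were richer in GC than those at other bound genes (medians 50.5 and 44.6%, permutation p = 4.000e-05), so a GC bias may contribute. Within the GC range of 46.5 to 53.5%, however, 34 ribosomal protein genes kept a higher median signal than 795 other bound genes (415 and 254, permutation p = 0.000400). Genes were not matched on GC inside that range. A remaining GC difference could therefore still contribute, and GC content alone was not excluded. Recovery of open, highly transcribed promoters by any immunoprecipitation, and recruitment of NHR-25 by other factors or at degenerate sites, stay open and untested, since neither the control nor another factor was analysed here.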

How the results depend on the processing

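Alternatives chosen after seeing the data were the pooled regions in place of the optimal list, leaving out mitochondrial regions, the transgene loci without each replicate, names as Ensembl gives them, and the nearest start with matched random lists. Of 359 results under alternatives, 316 kept their side of the threshold or stayed near the main value. Near meant within the replicate spread, or within 1.5 times for counts and for the share supported by all replicates. Single gene lists gave 216 of the 359 and kept theirs in 191, and a list that passed in neither setting counted as kept. Outside single gene lists and comparison motifs, 65 of 80 kept theirs and 15 moved. Some lists that passed in neither setting changed direction, such as germline markers (odds ratio 1.24 in the 2274 regions of highest signal). The shares of summits in promoters and on X, the FTZ-F1 family half-site and the ribosomal protein and heterochronic lists kept their direction and call under every alternative run for them. The odds ratio of the ribosomal protein list nevertheless fell to 5.56 with the nearest start. The number of optimal regions was 3347 on ce10. Of the ce11 optimal list, as many regions of highest signal were supported by all 3 replicates in 72.1% of cases, and the remaining 1201 in 7.24%. A fall with signal is built into that measure. Support by all replicates was 90.7% in the 2274 regions of highest signal, 33.0% with 50% overlap and 31.5% with the strongest 2274 regions per replicate. It was 82.5% with 2 times as many as in the main analysis. With 1 replicate left out, 62.2 to 64.8% of the regions were supported by both others. The overlap between replicates was 70.6% on ce10, 61.2% with 50% overlap, 59.1% with summits within 100 bp, 72.6% with the strongest 2274 and 61.8% with 2 times as many regions as in the main analysis, and 67.9 to 69.5% without each replicate. Its rank correlation was 0.609 with 50% overlap and 0.662 to 0.682 without each replicate. The signal threshold, the overlap rules and the number of regions compared move these shares by construction. In place of 3 gene lists, 5 passed with a window of 2000 bp, 10 with the nearest start, 7 with the nearest start and matched random lists and 5 with names as Ensembl gives them, which adds the histone list (Fisher's exact test, odds ratio 2.50, adjusted p = 0.0337) and the heat shock list (odds ratio 4.29, adjusted p = 0.0362). Hedgehog-related and Patched-related genes turned to an odds ratio of 1.79 (exact test, adjusted p = 0.0470) with the nearest start, and the Wnt and Hox list was also lost with pooled regions (adjusted p = 0.629); the cause was not tested. Leaving out a replicate also acts as a stricter filter, because regions then had to recur in both others. No paired analysis was possible because the design has 1 group. The depth is unknown, so its effect on weak sites could not be measured.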

Other observations

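The counts of this part were made after the lists had been examined, and none was planned.

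Besides the fixed lists, 183 classes of genes that share a name stem and have at least 10 members were tested in the same way, and 12 were bound more often and 23 less often than other genes (9 and 18 also against matched random lists). Some classes repeat genes of the fixed lists and add no independent result for them. The rpl and rps genes form most of the ribosomal protein list. The lin genes include lin-14, lin-28, lin-42, lin-46 and lin-66 of the heterochronic list and lin-39 of the Wnt and Hox list. The classes bound more often included rps (28 of 31) and rpl (38 of 49) genes of the ribosome, eif translation initiation factors (12 of 25, odds ratio 5.98, Fisher's exact test, adjusted p = 0.000638), rpn subunits of the proteasome (8 of 13, adjusted p = 0.00109), vha subunits of the vacuolar proton pump (9 of 20, adjusted p = 0.00525), cox subunits of cytochrome oxidase (7 of 15, adjusted p = 0.0148) and vps genes of vacuolar sorting (12 of 33, adjusted p = 0.00663). The lin genes, named for defects in cell lineage, were bound in 19 of 47 (odds ratio 4.41, Fisher's exact test, adjusted p = 0.000105). Classes bound less often included large families: clec lectins in 2 of 239 (Fisher's exact test, adjusted p = 6.642e-11), the chemoreceptor classes str in 1 of 193, srh in 4 of 220 and srbc in 0 of 70, and fbxa F-box genes in 4 of 170.

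With each summit given to its nearest start, 3140 genes had at least 1, of which 2358 had 1 and 141 had 4 or more. These counts are not corrected for the length of upstream sequence. The highest were at egl-27, a chromatin regulator gene (19 summits, 7 supported by all 3 replicates), nhr-25 (13, 10 supported), din-1, a co-repressor gene that acts with the nuclear receptor DAF-12 (12, 8 supported), and mdl-1, an E-box factor gene of the Mad family (11, 9 supported). The FOXO gene daf-16 had 8, of which 1 was supported by all 3, kin-20 had 8, and lin-14 and the TFEB homologue hlh-30 had 7 each. Other genes had counts as high, among them F49E2.5, ccch-1, mnk-1 and ppfr-1 with 9 each.

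Small RNA genes also lay close to bound sites. Within 200 bp of tRNA genes there were 80 summits, 6.49 times as many as length alone gives (exact binomial test, adjusted p = 3.991e-37), and 26 of them were supported by all 3 replicates. The counts were 66 against 8.22 at snoRNA genes (same exact test, adjusted p = 2.369e-36), 22 against 2.97 at snRNA genes (adjusted p = 2.048e-12) and 14 against 5.32 at miRNA genes (adjusted p = 0.00155). All 3 replicates supported 47, 15 and 7 of these, where 54.99% of all optimal regions had such support. The expected counts take only length into account. The strongest regions of replicates 1, 2 and 3 placed 13, 5 and 11 summits near miRNA genes, so replicate 2 showed no excess there. Promoter summits carried the extended half-site in 1.10% of cases and other summits in 1.75%, a difference that did not pass Fisher's exact test (p = 0.0774).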
